A study of Mus musculus with 12 samples.

How the data were processed

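Poly(A) RNA was sequenced from the prefrontal cortex of male C57BL/6J mice aged 14 weeks, 4 weeks after adeno-associated virus (AAV, a viral vector for gene delivery) had been injected on both sides into its dorsomedial part. Per the labels' protocols, virus was injected at 0.1 µL per min for 5 min. The 12 libraries fall into 3 groups of 4: a control virus carrying green fluorescent protein (GFP), a virus carrying GFP joined to the transthyretin gene Ttr, and a virus carrying a short hairpin RNA against Ttr together with GFP. The control vector and both Ttr vectors came from different suppliers, per the labels' protocols, so the source of the vector goes with the groups. The labels number 4 samples in each group and do not say that each came from its own mouse, so the p-values measure the spread between these samples, part of which may be technical.

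Per the labels' protocols, libraries were made from 500 ng of total RNA with poly(A) selection, a directional kit and adaptors carrying unique molecular identifiers. Bcl2fastq 2.20.0.422, UMI-tools, featureCounts and DESeq2 and the genome build GRCm38 (mm10) are named per the submitters' processing notes, with no role or order. The aligner, the annotation release, the strand setting of the counting and whether the identifiers were used to remove duplicates are not given in the sources used here. Values of 3 kinds were used. The authors deposited counts per gene, whole numbers that were not normalized. The deposited TPM values (abundance per transcript, scaled to one total in every library) equalled the authors' counts divided by a single length per gene and scaled, with all values of the 12003 genes compared (100%) within 0.01 on the log2 scale. The deposited variance-stabilised values lie on a log2 scale, with a floor of 7.10 at a count of 0 and slopes of 0.921 to 0.926 against log2 counts, and the transformation the authors ran is not stated. Of 55401 gene identifiers, 55141 were matched to symbols, and the other 260 held 0.00474% of all counts. Coordinates are those of the GENCODE mouse annotation on GRCm38.

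Changed genes were tested on the deposited counts with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling factors, the default expression filter by group and all 12 libraries in a single fit of 3 group means. Adjusted p-values are Benjamini-Hochberg values over the 18289 genes tested, with a threshold of 0.05. CPM (counts scaled to one library size, computed here) used the TMM factors. The square root of the common dispersion was 0.126 and the prior degrees of freedom were 4.10. Fixed gene lists, 33 in all, were tested with camera from limma 3.58.1 on log2 CPM (prior count 2), two-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Each list's effect is given as the mean difference of log2 CPM over its measured members, and its score in a library is the mean of its members' centred log2 CPM. The lists, the comparisons and the rule for naming genes were set before the data were examined. The rule named Ttr in each comparison, all genes that passed, the genes with the smallest p-values up to 10 per comparison (given as values where they did not pass), and up to 4 members with the smallest p-values of each list that passed. Genes or values outside that rule are said to be chosen after their values were seen. A gene that the rule named is left out of the text on a request from outside the analysis.

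On simulated counts with 200 changed genes, the same steps recovered 67.2% of 1.5-fold, 92.5% of 2-fold and 100% of 4-fold changes in the overexpression comparison (18135 genes), with 10 calls among unchanged genes. In the knockdown comparison (18105 genes) the shares were 65.7%, 88.1% and 100%, with 8 such calls. These simulations hold no structure between libraries beyond the groups, so they give the reach of the test for libraries that differ in the tested effects alone.

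Alternatives covered other scalings, filters and tools (DESeq2 1.42.0, limma-voom), the deposited TPM and variance-stabilised values, a fold threshold, robust dispersions, fits of only the 2 groups compared, the replicate number as a block, other list tests and each library left out in turn. Alternatives chosen after seeing the data were a striatal or a mural and meningeal score per library as covariate, and 2 sets of libraries left out. No pair of libraries of a group agreed within sampling noise, with chi-square values per degree of freedom of 5.37 to 28.4 over 18 pairs. Genes that share reads with close copies (H2-Q6 and H2-Q7, Ifit3 and Ifit3b, Hba-a1 and Hba-a2, immunoglobulin segments) and genes that overlap on either strand are uncertain. Counting intervals and floors cover counting error only. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Behaviour and vitamin B12 levels were not analysed here.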

Results

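The data are gene counts from 12 libraries of mouse prefrontal cortex, 4 from mice given the GFP control virus, 4 from mice given the Ttr overexpression virus and 4 from mice given the Ttr knockdown virus. Transthyretin, the product of Ttr, carries thyroid hormone and, bound to retinol-binding protein, retinol in blood and cerebrospinal fluid. In the brain it is made mainly by the choroid plexus epithelium. The series title sets the work in the context of vitamin B12 and resilience to stress. Total counts were 24362582, 23955545, 37166146 and 22911948 in control replicates 1 to 4, and 32119771, 33435207, 27644043 and 21960429 in overexpression replicates 1 to 4. They were 20917157, 25136816, 34606413 and 19879629 in knockdown replicates 1 to 4. The first 3 principal components of log2 CPM held 25.5%, 18.7% and 12.97% of the variance.

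Ttr was far higher with the overexpression virus than in both other groups, where its counts were low. The gene (ENSMUSG00000061808) lies on the plus strand of chromosome 18 at 20665280 to 20674321 (GRCm38). It had 20940, 8527, 7263 and 2121 counts in overexpression replicates 1 to 4, against 14, 200, 18 and 18 in the controls and 3, 47, 29 and 13 in the knockdown libraries. The means were 314 ± 231 CPM (SD, n = 4) with overexpression, 2.59 ± 3.94 CPM in controls and 0.873 ± 0.718 CPM with knockdown. Ttr rose by 7.01 ± 0.81 on the log2 scale (SE) in overexpression against control, with an edgeR adjusted p of 0.0168. It was 8.42 ± 0.91 higher in overexpression than in knockdown, with an edgeR adjusted p of 0.00774. Reads from the virus and from the mouse gene were not separated in the counts. Knockdown against control gave -1.41 ± 1.16 (edgeR adjusted p = 0.936), which rested on control replicate 2. Without that library the value was 0.60, and the CPM of the other 3 controls (0.49 to 0.78) lay within the range of the knockdown libraries (0.15 to 1.86). A reduction of Ttr was thus not detectable at this depth, and the counts of Ttr do not check the knockdown label.

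**Figure D1:**
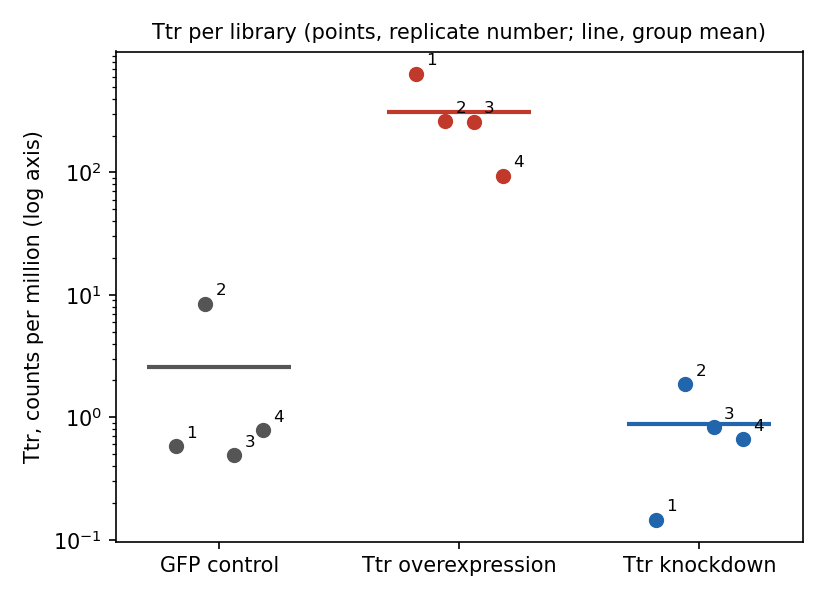
Ttr in each library, in CPM on a log axis, by group, with the replicate number beside each point and a line at the group mean. The 4 overexpression libraries lie between 94.2 and 639 CPM, and the highest of the other 8 libraries is control replicate 2 at 8.50 CPM.

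The call on Ttr in overexpression against control was lost, with values nearly as large, when single libraries were left out. The log2 value was 6.69 without control replicate 1, 6.58 without control replicate 3, 6.73 without control replicate 4 and 7.08 without overexpression replicate 3, with edgeR adjusted p of 0.143, 0.0922, 0.162 and 0.0506. In overexpression against knockdown the call on Ttr was lost without knockdown replicate 1 (8.13), knockdown replicate 2 (9.04) or knockdown replicate 3 (8.36). Without those libraries the edgeR adjusted p was 0.093, 0.064 and 0.093.

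The comparison of overexpression with control asks what raised Ttr does to the cortex. Markers of vessel wall and meninges, of reactive astrocytes, of antigen presentation and of lymphocytes rose as groups in camera with a preset correlation. With an estimated correlation 0 of the 33 lists passed, and these 4 had adjusted p = 0.178, 0.178, 0.338 and 0.244 with an estimated correlation. Ttr was the only one of 18289 genes to pass the edgeR test by itself. DESeq2 called 40 genes and limma-voom 0, and 1145 genes, 838 of them higher, had an unadjusted edgeR p below 0.05 where chance gives 914. EdgeR called 4 genes without overexpression replicate 2, and 0 without control replicates 1, 3 or 4 or overexpression replicate 3. The genes with the smallest p-values after Ttr all had higher means with overexpression. Tagln, a smooth muscle cytoskeletal protein, had 9.32 ± 4.24 CPM against 3.26 ± 0.335 in controls (1.5 ± 0.26 on the log2 scale, edgeR adjusted p = 0.297). The other 8 of these genes had the same adjusted p. They were Igfbp2 (0.80), which binds insulin-like growth factors, Cp (0.99), the copper carrier ceruloplasmin, and Aox3 (1.51), an aldehyde oxidase. Myh11 (0.87) and Cnn2 (0.80) encode contractile proteins, Mrc1 (1.11) marks perivascular macrophages, Slc6a13 (1.33) is a GABA transporter of the meninges and Slc16a12 (0.86) is a monocarboxylate transporter.

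Genes of mural and meningeal cells rose in overexpression, with a mean of 1.00 on the log2 scale and 19 of 20 measured members positive (camera adjusted p = 1.79e-20). In edgeR 16 of these passed when adjusted over the list alone and 0 over all genes tested, while DESeq2 called Tagln, Igfbp2, Slc6a13, Myh11 and Acta2 over all genes, as did edgeR with no filter on low counts. The call was lost with the correlation estimated for each list (adjusted p = 0.178 with an estimated correlation). The scores of the 4 overexpression libraries, 0.303 to 1.015, lay above those of the 4 controls, -0.967 to 0.138. The score thus goes with the group, and fits with it as covariate cannot fully tell the score from the group. Genes of reactive astrocytes rose by a mean of 0.51, with 23 of 28 members positive and 9 passing when adjusted over the list alone (camera adjusted p = 7.20e-10, and adjusted p = 0.178 with an estimated correlation). Serping1, an inhibitor of complement, had 11.2 ± 4.55 CPM against 3.03 ± 1.54, and Steap4, a metalloreductase, 0.575 ± 0.0931 against 0.254 ± 0.114. Steap4 rested on 2 to 11 counts per control library. Gfap, a member chosen after its values were seen, had 3139 to 6339 counts in overexpression libraries and 3136 to 5415 in controls, ranges that overlap. Choroid plexus genes rose by a mean of 0.63, with 16 of 17 members positive and 1 passing when adjusted over the list alone (camera adjusted p = 1.24e-05, and adjusted p = 0.178 with an estimated correlation). Members of that list are also made elsewhere in the brain. Slc13a4, a sulphate transporter also of meningeal cells, had 13.9 ± 4.53 CPM against 3.75 ± 2.45, while Kcnj13, a potassium channel of the epithelium, had 1.24 ± 0.564 against 0.344 ± 0.374. With the mural and meningeal score of each library as covariate, the means of reactive astrocyte, choroid plexus and retinoid genes were 0.14, 0.081 and 0.15 and their calls ended, while Slc13a4 and Kcnj13 turned to -0.09 and -0.65 on the log2 scale. Retinoid transport and signalling genes rose by a mean of 0.35, with 15 of 19 members positive and 1 passing when adjusted over the list alone (camera adjusted p = 0.00531, and adjusted p = 0.244 with an estimated correlation). Aldh1a2, which makes retinoic acid and is a meningeal marker as well, had 11.0 ± 3.51 CPM against 2.99 ± 1.60. The retinoid call ended without control replicate 1 (0.31, camera adjusted p = 0.0526).

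Immune genes rose too, to very different levels between the overexpression libraries. Antigen presentation genes had a mean of 1.45 with all 21 members positive (camera adjusted p = 3.76e-12), and 17 passed when adjusted over the list alone. The list had an adjusted p = 0.338 with an estimated correlation. The class II genes H2-Aa, H2-Ab1 and H2-Eb1, which present peptides to T cells, had log2 values of 4.14, 4.14 and 3.93. Cd74, which encodes the invariant chain of class II molecules, had 4.13, and the SEs of all were 0.86 to 0.91. Cd74 had 42.2, 9.20, 17.7 and 262 CPM in overexpression replicates 1 to 4 and 2.34 to 7.34 in the controls. Lymphocyte genes had a mean of 1.27 with 10 of 11 measured members positive and 6 passing when adjusted over the list alone (camera adjusted p = 1.28e-05, and adjusted p = 0.244 with an estimated correlation). Igkc, the kappa light chain of antibodies, had 73.8, 3.42, 2.04 and 24.6 CPM in overexpression replicates 1 to 4 and at most 3.34 in the other 8 libraries. Cd8a, a coreceptor of cytotoxic T cells, had 1.13 ± 1.57 CPM against 0.0735 ± 0.0208, and Ccl5, a chemokine of T cells, 2.14 ± 3.09 against 0.140 ± 0.0568. Their control values rested on 1 to 3 and 2 to 8 counts per library. In overexpression replicate 4 they had 78 and 152 counts, against 4 to 16 and 8 to 33 in the other overexpression libraries. Interferon-stimulated genes rose by a mean of 0.91 with all 39 members positive and 0 passing in edgeR adjusted over the list alone (camera adjusted p = 6.79e-09, and adjusted p = 0.562 with an estimated correlation). The interferon scores of overexpression replicates 1 and 2 (-0.630 and -1.06) lay within those of the controls (-1.31 to -0.567), and those of replicates 3 and 4 were 0.688 and 0.892. Zbp1, a sensor of nucleic acids, had 2.48 ± 2.80 CPM against 0.241 ± 0.0357. Activated microglia genes rose by a mean of 0.55, with 23 of 24 positive and 2 passing when adjusted over the list alone (camera adjusted p = 1.75e-05, and adjusted p = 0.498 with an estimated correlation). The complement gene C3 and the lysozyme gene Lyz2 had log2 values of 3.26 ± 0.85 and 0.98 ± 0.31. Without overexpression replicate 4 the mean was 0.88 for antigen presentation, 0.59 for interferon-stimulated genes and 0.26 for activated microglia, and all 3 lists still passed. With the mural and meningeal score as covariate the means were 0.88, 0.0039 and 0.19, and the interferon and microglia calls ended.

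A further 4 lists rose in overexpression, and single libraries moved each of them by over 1.5 times. Endothelial genes rose by a mean of 0.22 (17 of 18 positive, camera adjusted p = 2.81e-06, and adjusted p = 0.410 with an estimated correlation), and by 0.14 without overexpression replicate 3. Vwf, a clotting factor of vessel lining, had 16.5 ± 3.35 CPM against 11.0 ± 0.654. Immediate early genes rose by 0.23 (22 of 27 positive, camera adjusted p = 0.000120, and adjusted p = 0.410 with an estimated correlation), and by 0.11 without overexpression replicate 4. Fos had 16.6 ± 9.51 CPM against 8.42 ± 1.36, with ranges that overlap. Nr4a1, an activity-induced nuclear receptor, had 56.6 to 76.2 CPM against 45.3 to 56.1 in controls, with no overlap, and did not pass. Homeostatic microglia genes rose by 0.22 (21 of 22 positive, camera adjusted p = 0.00145, and adjusted p = 0.605 with an estimated correlation). Their mean was 0.35 without overexpression replicate 2 and 0.051 without overexpression replicate 4, where the call ended. Fcrls, a member of that list, pointed the other way, with 15.1 to 24.7 CPM in overexpression against 23.3 to 28.7 in controls. Ependymal genes rose by 0.52 (11 of 12 positive, camera adjusted p = 0.0117, and adjusted p = 0.588 with an estimated correlation). That call ended without control replicate 1 (0.39), control replicate 3 (0.35) or overexpression replicate 3 (0.25), and the mean was 0.88 without control replicate 4 and 0.82 without overexpression replicate 2. The endothelial, homeostatic microglia and ependymal calls ended with the mural and meningeal score as covariate (means 0.049, 0.069 and 0.61, camera adjusted p = 0.593, 0.948 and 0.0651), while immediate early genes still passed (0.34). In each of these 4 lists edgeR passed 0 genes adjusted over the list alone.

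Other lists fell in overexpression. Myelin genes fell by a mean of 0.23 with all 22 members negative (camera adjusted p = 0.00201, and adjusted p = 0.605 with an estimated correlation). The call ended without control replicate 2 (-0.0055) or overexpression replicate 2 (-0.13), and the mean was -0.39, -0.40 and -0.14 without control replicates 1, 3 and 4. Excitatory neuron genes fell by 0.12 (14 of 20 negative, 1 passing when adjusted over the list alone, camera adjusted p = 0.0141, and adjusted p = 0.338 with an estimated correlation), a call that ended without control replicate 1 (-0.12) or overexpression replicate 4 (-0.11). Nptx1, a secreted synaptic protein, had 428 ± 43.0 CPM against 575 ± 74.3, and Tbr1, a transcription factor of deep-layer neurons, 150 ± 18.3 against 180 ± 16.8. Haemoglobin and other blood cell genes fell by 0.36 (5 of 5 negative, camera adjusted p = 0.00681, and adjusted p = 0.519 with an estimated correlation), and the call ended without control replicate 1 (-0.30), control replicate 3 (-0.24) or overexpression replicate 3 (-0.23). Oxidative phosphorylation genes fell by 0.06 (53 of 59 negative, camera adjusted p = 1.39e-05, and adjusted p = 0.588 with an estimated correlation), with means of -0.093, -0.031, -0.035 and -0.093 without control replicate 3, control replicate 4, overexpression replicate 1 and overexpression replicate 4. Presynaptic genes fell by 0.05 (22 of 26 negative, camera adjusted p = 0.00152, and adjusted p = 0.562 with an estimated correlation), with means of -0.021, -0.11 and -0.023 without overexpression replicates 1, 2 and 3. Ribosomal protein genes fell by 0.06 (39 of 51 negative, camera adjusted p = 0.00716, and adjusted p = 0.605 with an estimated correlation). Their call ended without control replicate 2 (-0.039), control replicate 4 (-0.027) or overexpression replicate 2 (-0.027), and the mean was -0.10 without control replicate 3 and -0.094 without overexpression replicate 4. Some members had few counts per library, as did Rps16 (17 to 41) and Rpl38 (21 to 50), while Rps2 had 254 to 391. The cause of such low counts was not tested. Unfolded protein response genes fell by 0.04 (22 of 28 negative, camera adjusted p = 0.0202, and adjusted p = 0.588 with an estimated correlation). That call ended without control replicate 3 (-3.1e-05), overexpression replicate 1 (-0.033) or overexpression replicate 3 (-0.021), and the mean was -0.061, -0.058 and -0.061 without control replicate 1, control replicate 2 and overexpression replicate 4. The means of myelin, excitatory neuron, presynaptic and ribosomal protein genes turned, with the mural and meningeal score as covariate, to 0.038, 0.083, 0.0063 and 0.032 and did not pass. Under that covariate oxidative phosphorylation genes turned to 0.073 and passed in that opposite direction (camera adjusted p = 0.000396), so their fall depended on that choice. Besides the gene in the excitatory list, edgeR passed 0 genes of these lists adjusted over the list alone.

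The comparison of knockdown with control asks what the hairpin against Ttr does to the cortex. Immediate early genes, which neurons switch on within minutes of activity, and interferon-stimulated genes rose as groups in camera with a preset correlation. They had adjusted p = 0.0782 and 0.385 with an estimated correlation, where 0 of the 33 lists passed. Nr4a1 (ENSMUSG00000023034, plus strand of chromosome 15, 101254269 to 101274795), an activity-induced nuclear receptor, was the only gene to pass the edgeR test. It rose by 1.06 ± 0.13 on the log2 scale, from 51.1 ± 4.92 CPM to 107 ± 18.1 (SD, n = 4; edgeR adjusted p = 0.0242). It was higher in each knockdown library than in each control. DESeq2 called 42 genes and limma-voom 1, and 1039 genes, 705 of them higher, had an unadjusted edgeR p below 0.05 where chance gives 914. The call on Nr4a1 was lost without control replicates 1, 2, 3 or 4, where its log2 values were 1.04, 1.09, 1.11 and 1.01, or without knockdown replicates 1, 2 or 3, where they were 0.99, 1.03 and 1.03. In those 7 fits edgeR called 0 genes, while it called 10 without knockdown replicate 4, 2 without overexpression replicate 2 and 3 without overexpression replicate 4. With the replicate number as a block edgeR called 0 genes as well, so the call on Nr4a1 ended there too.

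Immediate early genes had a mean of 0.63 with 24 of 27 members positive, and 18 passed when adjusted over the list alone (camera adjusted p = 7.37e-24, and adjusted p = 0.0782 with an estimated correlation). All 4 knockdown scores, 0.038 to 0.540, lay above the control scores, -0.356 to -0.18. Egr2, a zinc finger transcription factor, had 8.45 ± 2.38 CPM against 1.86 ± 0.296 in controls (2.17 ± 0.34 on the log2 scale, edgeR adjusted p = 0.190). Egr4, of the same family, had 31.7 ± 6.31 CPM against 16.4 ± 1.10, and Tiparp, a poly(ADP-ribose) polymerase, 17.8 ± 2.53 against 12.1 ± 0.635. Other genes with small p-values were Trib1 (0.56) and Stk40 (0.38), which encode pseudokinases, and Nfil3 (0.51), a leucine zipper transcription factor. Midn (0.51), which encodes midnolin, and Spry4 (0.55), which dampens growth factor signalling, were others. None of these passed over all genes in the edgeR fit reported (edgeR adjusted p = 0.234 for each of Trib1, Stk40, Nfil3, Midn, Spry4, Egr4 and Tiparp), while DESeq2 called each of them. With no filter on low counts edgeR called Egr2, Egr4, Tiparp, Trib1 and Midn, but not Stk40, Nfil3 or Spry4. Glucocorticoid response genes rose by a mean of 0.11, with 16 of 22 members positive and 2 passing when adjusted over the list alone (camera adjusted p = 0.010, and adjusted p = 0.333 with an estimated correlation). Both were members of the immediate early list too, the clock gene Per1, with 97.5 ± 16.6 CPM against 62.7 ± 9.66, and the phosphatase gene Dusp1, with 38.7 ± 8.10 against 24.9 ± 3.75. The glucocorticoid call ended without control replicate 1 (0.071, camera adjusted p = 0.0594).

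Interferon-stimulated genes had the largest mean of the 33 lists in knockdown, 1.90, with all 39 members positive and 37 passing when adjusted over the list alone (camera adjusted p = 2.12e-34, and adjusted p = 0.385 with an estimated correlation). Their scores were 0.230, 0.974, -0.092 and 2.736 in knockdown replicates 1 to 4 and -1.31 to -0.567 in controls. Usp18, which removes the ubiquitin-like modifier Isg15, had 6.26, 9.05, 3.94 and 51.8 CPM in knockdown replicates 1 to 4 and 0.52 to 1.5 in controls. Oas2, a sensor of double-stranded RNA, had 2.48, 3.91, 2.03 and 17.3 CPM against 0.43 to 0.75. Irf9, a transcription factor of the interferon response, had 41.7 ± 31.7 CPM against 8.73 ± 1.54, and Ifi27 67.0 ± 17.9 against 30.6 ± 2.22. Antigen presentation genes rose by 0.80 with 20 of 21 members positive and 0 passing in edgeR adjusted over the list alone (camera adjusted p = 1.08e-05, and adjusted p = 0.547 with an estimated correlation). The class I genes B2m, Tap1 and H2-D1 had log2 values of 1.15 ± 0.41, 1.68 ± 0.65 and 1.24 ± 0.50. Without knockdown replicate 4 the mean of antigen presentation genes was 0.52 and that of interferon-stimulated genes 1.31, and both lists still passed.

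**Figure D2:**
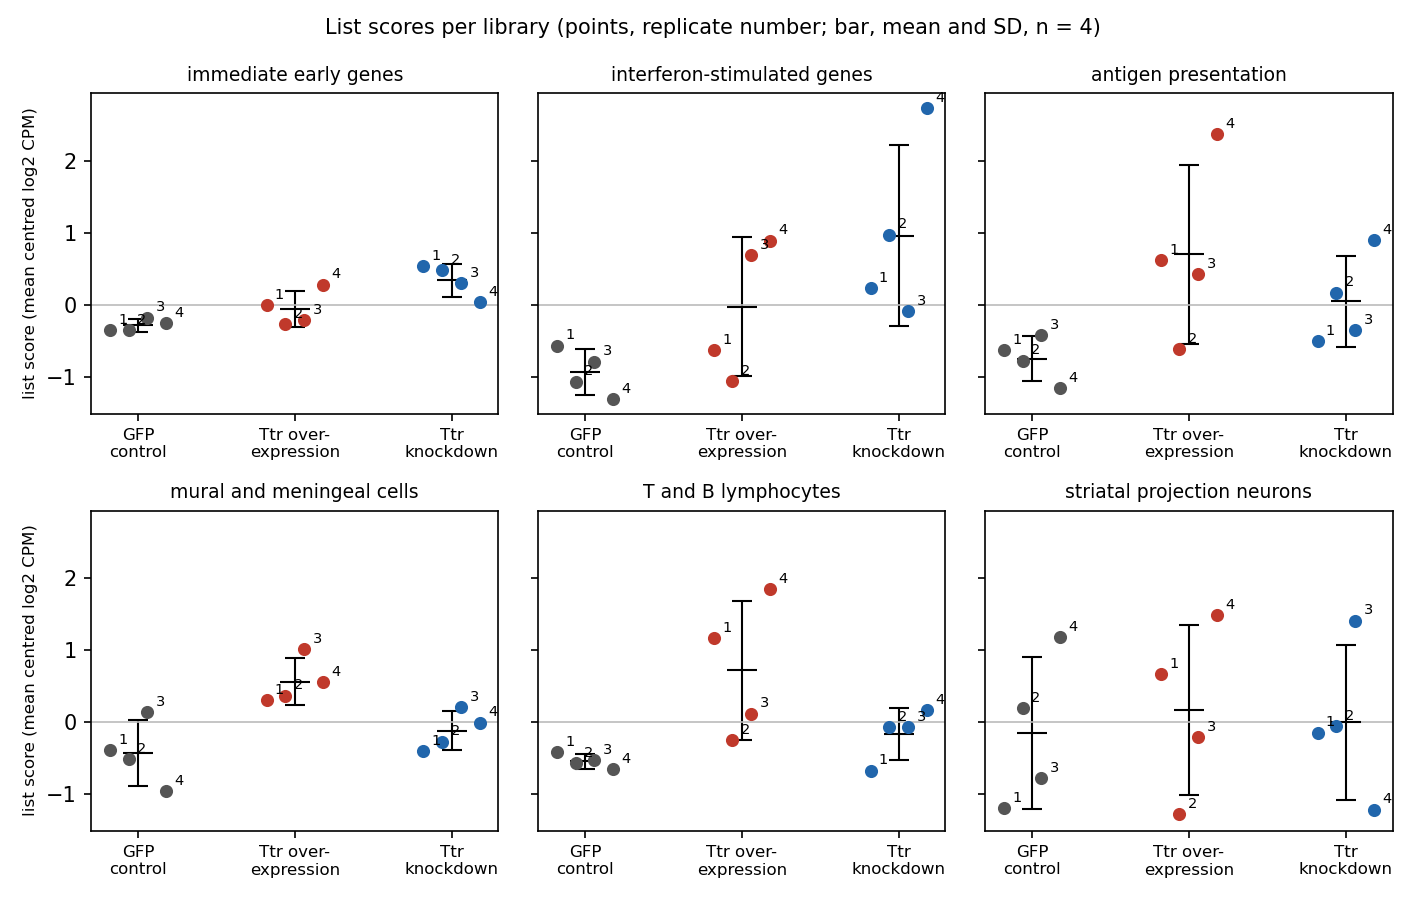
Score of 6 gene lists in each library (mean centred log2 CPM of the members), by group, with replicate numbers beside the points and the mean and SD of 4 libraries. Immediate early scores of knockdown libraries (0.038 to 0.540) lie above all 4 controls, interferon scores reach 2.736 in knockdown replicate 4, and striatal scores range from -1.281 to 1.482 within the overexpression group.

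Myelin genes fell by a mean of 0.43 in knockdown with all 22 members negative (camera adjusted p = 7.88e-08, and adjusted p = 0.547 with an estimated correlation). Olig2, a transcription factor of the oligodendrocyte lineage, had 24.1 ± 1.77 CPM against 31.5 ± 6.49. The mean was -0.20 without control replicate 2 and -0.20 without knockdown replicate 4. Endothelial genes rose by 0.19 (18 of 18 positive, camera adjusted p = 9.96e-06, and adjusted p = 0.494 with an estimated correlation), and by 0.12 without knockdown replicate 4. Pecam1, an adhesion molecule of vessel lining, had 21.9 ± 2.00 CPM against 17.8 ± 0.494. Homeostatic microglia genes rose by 0.27 (21 of 22 positive, camera adjusted p = 1.23e-05, and adjusted p = 0.547 with an estimated correlation), and by 0.14 without knockdown replicate 4. Ctss, a lysosomal protease of microglia, had 125 ± 51.0 CPM against 76.4 ± 4.53. Reactive astrocyte genes rose by 0.27 (23 of 28 positive, camera adjusted p = 0.00118, and adjusted p = 0.494 with an estimated correlation), and the call ended with the mural and meningeal score as covariate (0.16). Gfap, the astrocyte filament protein of that list, pointed the other way, with 112 ± 21.5 CPM against 165 ± 29.0. Mural and meningeal genes rose by 0.31 (15 of 20 positive, camera adjusted p = 0.00116, and adjusted p = 0.598 with an estimated correlation). The call ended without control replicate 4 (0.14), and the mean was 0.50 without control replicate 3 and 0.20 without knockdown replicate 3. In these 5 lists edgeR passed 0 genes adjusted over the list alone.

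The remaining calls in knockdown each ended when single libraries were left out. Inhibitory neuron genes rose by 0.20 (20 of 23 positive, camera adjusted p = 0.0189, and adjusted p = 0.494 with an estimated correlation), with 0.16, 0.18 and 0.12 and no call without control replicate 1, control replicate 3 and knockdown replicate 2. Ndnf and Calb2, markers of interneuron subtypes, had log2 values of 1.08 ± 0.33 and 1.04 ± 0.38. Excitatory neuron genes fell by 0.14 (13 of 20 negative, camera adjusted p = 0.0158, and adjusted p = 0.494 with an estimated correlation), with -0.15 without control replicate 1 and -0.057 without knockdown replicate 4. Tbr1 had 143 ± 14.3 CPM against 180 ± 16.8. Genes of the corticotropin-releasing hormone system rose by 0.16 (6 of 6 positive, 1 passing when adjusted over the list alone, camera adjusted p = 0.0229, and adjusted p = 0.494 with an estimated correlation). The member that passed over the list was Adcyap1r1, a receptor for the peptide PACAP, with 216 ± 17.8 CPM against 184 ± 9.98. The mean was 0.10, 0.13, 0.16, 0.13 and 0.10 without control replicate 2, control replicate 4 and knockdown replicates 1, 2 and 4. Activated microglia genes rose by 0.26 (20 of 24 positive, camera adjusted p = 0.0341, and adjusted p = 0.700 with an estimated correlation), with 0.22, 0.21, 0.25 and 0.11 without control replicates 1 and 4 and knockdown replicates 2 and 4. Astrocyte identity genes rose by 0.12 (15 of 18 positive, camera adjusted p = 0.0158, and adjusted p = 0.547 with an estimated correlation), with 0.057 without control replicate 4 and 0.071 without knockdown replicate 4. Mitochondrially encoded genes rose by 0.10 (13 of 15 positive, camera adjusted p = 0.0186, and adjusted p = 0.674 with an estimated correlation). Their mean was 0.084, 0.013 and 0.014, with no call, without control replicate 2, control replicate 4 and knockdown replicate 4, and 0.16 without control replicate 3. Presynaptic genes fell by 0.07 (21 of 26 negative, camera adjusted p = 0.00901, and adjusted p = 0.607 with an estimated correlation), with -0.057 and -0.070 without control replicate 3 and knockdown replicate 3. Calls that ended with the mural and meningeal score as covariate were those on excitatory neuron (-0.078), corticotropin-releasing hormone (0.15), activated microglia (0.15), astrocyte identity (0.039), mitochondrially encoded (0.0040) and presynaptic genes (-0.056). In these lists other than the hormone system, edgeR passed 0 genes adjusted over the list alone.

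Overexpression against knockdown sets both Ttr viruses side by side. Ttr was the only gene to pass in edgeR, DESeq2 called 4 genes (Ttr, Nr4a1, Ifi27 and Ccl8) and limma-voom 0, and 932 genes had an unadjusted edgeR p below 0.05 where chance gives 914. EdgeR called 0 genes without knockdown replicates 1, 2 or 3, and 2 without overexpression replicate 2 or knockdown replicate 4. Immediate early genes were lower in overexpression by a mean of 0.39, with 25 of 27 members negative and 10 passing when adjusted over the list alone (camera adjusted p = 4.86e-14, and adjusted p = 0.344 with an estimated correlation). Nr4a1 had 67.6 ± 9.24 CPM in overexpression and 107 ± 18.1 in knockdown (-0.66 ± 0.13 on the log2 scale, edgeR adjusted p = 0.855, and DESeq2 adjusted p = 0.00748), and passed in edgeR without knockdown replicate 4 (-0.77). Fosl2, a partner of Jun proteins, had 33.3 ± 3.41 against 44.1 ± 2.68, and P4ha1, a collagen prolyl hydroxylase subunit, 40.4 ± 0.877 against 47.5 ± 2.41. Mural and meningeal genes were higher by 0.68, with 19 of 20 positive and 9 passing when adjusted over the list alone (camera adjusted p = 1.46e-13, and adjusted p = 0.501 with an estimated correlation). The collagen genes Col1a2 and Col3a1 had 24.8 ± 4.93 and 4.11 ± 1.70 CPM against 13.2 ± 3.46 and 1.44 ± 0.755. Clec3b, which encodes tetranectin, had 2.28 ± 0.719 against 1.02 ± 0.163, and Arr3, a cone arrestin, 0.956 ± 0.113 against 0.453 ± 0.0750. Choroid plexus genes were higher by 0.39 (14 of 17 positive, 0 passing in edgeR adjusted over the list alone, camera adjusted p = 0.00150, and adjusted p = 0.501 with an estimated correlation), but by 0.010 and with no call with the mural and meningeal score as covariate.

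Immune lists moved apart between the Ttr viruses. Interferon-stimulated genes were lower in overexpression by 0.99 (36 of 39 negative, 1 passing when adjusted over the list alone, camera adjusted p = 1.21e-13, and adjusted p = 0.654 with an estimated correlation), with -0.40 without knockdown replicate 4 and -0.65 without overexpression replicate 2. Lymphocyte genes were higher by 0.88 (11 of 11 positive, 2 passing when adjusted over the list alone, camera adjusted p = 0.00208, and adjusted p = 0.654 with an estimated correlation), a call that ended without overexpression replicate 4 (0.50). Antigen presentation genes were higher by 0.65 (17 of 21 positive, 6 passing when adjusted over the list alone, camera adjusted p = 0.00939, and adjusted p = 0.702 with an estimated correlation). That call ended without overexpression replicate 4 (0.089), knockdown replicate 1 (0.46) or knockdown replicate 3 (0.51), and the mean was 1.09 without overexpression replicate 2. Reactive astrocyte genes were higher by 0.23 (20 of 28 positive, 3 passing when adjusted over the list alone, camera adjusted p = 0.00150, and adjusted p = 0.654 with an estimated correlation), and the call ended without overexpression replicate 4 (0.16). Gfap had 195 ± 77.3 CPM in overexpression and 112 ± 21.5 in knockdown, and Vim, another filament protein, 50.3 ± 13.3 and 33.7 ± 4.17. Activated microglia genes were higher by 0.29 (17 of 24 positive, 0 passing in edgeR adjusted over the list alone, camera adjusted p = 0.0424, and adjusted p = 0.702 with an estimated correlation). Their call ended without overexpression replicates 3 (0.29) or 4 (0.0079) or knockdown replicates 1 (0.20), 2 (0.31) or 3 (0.21), and the mean was 0.53 and 0.44 without overexpression replicate 2 and knockdown replicate 4. The mural and meningeal score as covariate ended the calls on antigen presentation (0.26) and activated microglia genes (0.045), and with it reactive astrocyte genes turned to -0.015 and did not pass. Interferon-stimulated genes still passed under that covariate with a larger mean (-1.61), as did lymphocyte genes (0.84).

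The other lists that passed between overexpression and knockdown had smaller means, and edgeR passed 0 of their genes adjusted over the list alone. Myelin genes were higher by 0.19 (21 of 22 positive, camera adjusted p = 0.0263, and adjusted p = 0.720 with an estimated correlation). The call ended without overexpression replicates 3 (0.11) or 4 (0.14) or knockdown replicate 4 (-0.038), and the mean was 0.30 and 0.32 without overexpression replicate 2 and knockdown replicate 3. Nuclear-retained RNAs, a sign of RNA quality, were higher by 0.17 (9 of 10 positive, camera adjusted p = 0.0146, and adjusted p = 0.654 with an estimated correlation), with 0.098, 0.094 and 0.15 and no call without overexpression replicate 1, knockdown replicate 1 and knockdown replicate 2. Mitochondrially encoded genes were lower by 0.12 (14 of 15 negative, camera adjusted p = 0.00258, and adjusted p = 0.654 with an estimated correlation), with -0.094 and -0.030 and no call without overexpression replicate 4 and knockdown replicate 4. Ribosomal protein genes were lower by 0.06 (34 of 51 negative, camera adjusted p = 0.00274, and adjusted p = 0.654 with an estimated correlation). Their call ended without overexpression replicate 2 (-0.031) or knockdown replicate 4 (-0.042), and the mean was -0.091 and -0.040 without overexpression replicate 4 and knockdown replicate 1. Oxidative phosphorylation genes were lower by 0.04 (45 of 59 negative, camera adjusted p = 0.0121, and adjusted p = 0.720 with an estimated correlation). The call ended without overexpression replicates 1 (-0.0084) or 3 (-0.017) or knockdown replicates 1 (-0.024) or 4 (-0.029), and the mean was -0.065 and -0.066 without overexpression replicates 2 and 4. Their mean turned to 0.052 with the mural and meningeal score as covariate and passed in that opposite direction (camera adjusted p = 0.00355), and the calls on nuclear-retained RNAs (0.060) and ribosomal protein genes (-0.00019) ended. Myelin and mitochondrially encoded genes still passed under that covariate, with larger means of 0.38 and -0.33.

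**Figure D3:**
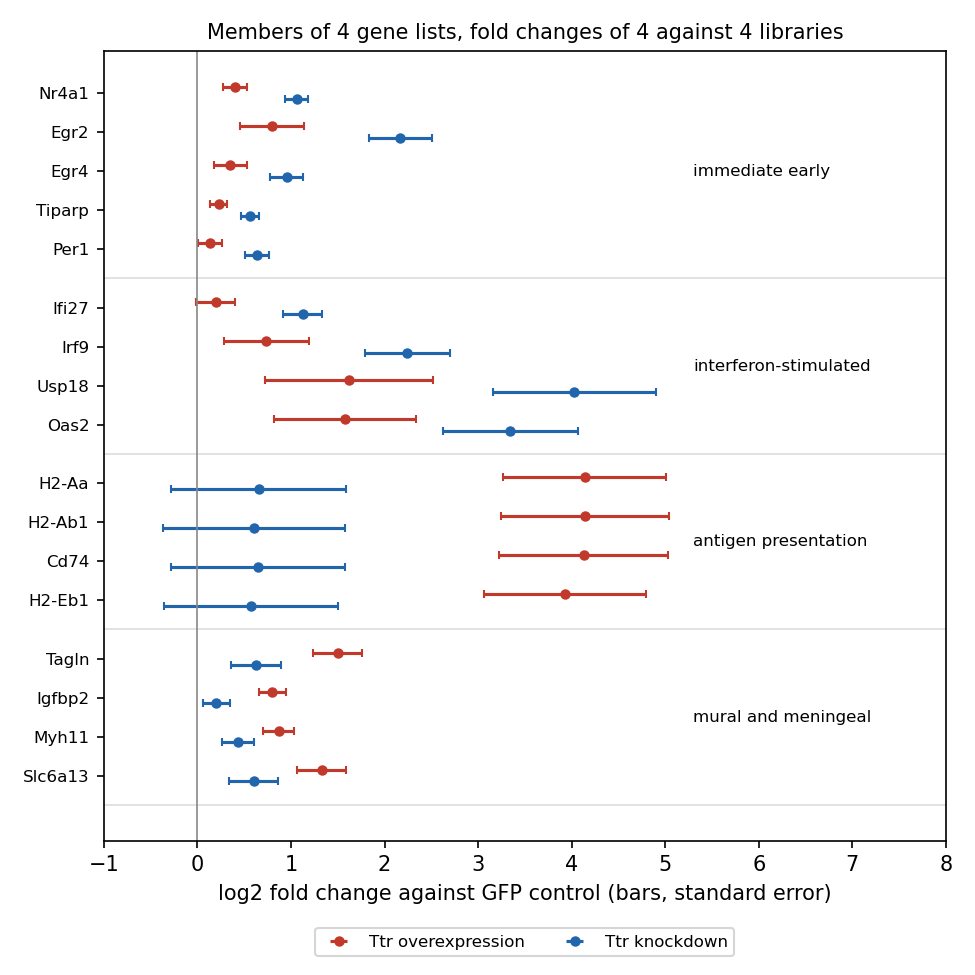
Log2 fold changes against GFP control, with standard errors, of 17 members of 4 gene lists in overexpression and in knockdown, each 4 against 4 libraries. Nr4a1 at 1.06 in knockdown is the only value drawn that passed over all genes tested in the edgeR fit reported. DESeq2, and edgeR with no filter on low counts, also called others, among them the class II genes. The class II genes H2-Aa, H2-Ab1 and H2-Eb1 and the invariant chain gene Cd74 have edgeR values of 3.93 to 4.14 in overexpression.

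Of the processes that the title or the functions of transthyretin bring in, several did not pass in any comparison. Vitamin B12, folate and methionine cycle genes had means of 0.04, 0.08 and -0.04 in overexpression against control, knockdown against control and overexpression against knockdown (camera adjusted p = 0.814, 0.0954 and 0.145), with 0, 1 and 0 members passing in edgeR adjusted over the list alone. Thyroid hormone transport and response genes had means of -0.09, -0.02 and -0.07, with a median of 0.01 in the last comparison (camera adjusted p = 0.0516, 0.412 and 0.321), with 0 members passing in each by that count. Markers of striatal projection neurons, which the dissected cortex can hold from the neighbouring striatum, had means of 0.32, 0.15 and 0.17 (camera adjusted p = 0.178, 0.667 and 0.379). Their scores ran from -1.281 to 1.482 in overexpression libraries, -1.221 to 1.407 in knockdown libraries and -1.198 to 1.179 in controls. Drd2, a dopamine receptor of striatal neurons, had between 1.10 and 39.7 CPM. In all, 19, 16 and 13 of the 33 lists passed in the 3 comparisons, with 0, 0 and 0 passing with an estimated correlation. Fry, which asks whether the genes of a list move one way, passed 0, 1 and 0 lists, the 1 being immediate early genes in knockdown (fry adjusted p = 0.0140). For changes in either direction fry passed 2, 1 and 0 lists, which were mural and meningeal genes and reactive astrocytes in overexpression and immediate early genes in knockdown. Scores of the groups did not overlap in 5, 2 and 1 of the 33 lists, where 2.86% (0.943 lists) would do so by chance.

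The values against control in overexpression and in knockdown were compared over the 18289 genes. Their correlation across genes was 0.618 and 68.6% had the same sign, where genes are not independent replicates. Both comparisons use the same controls, and 50 simulations of unchanged groups gave a correlation of 0.499 ± 0.0118 (SD) and 66.7% of equal signs. The covariance was 0.0528 against a simulated 0.0215 ± 0.000762, a difference of 0.0313. The simulations drew each gene by itself, with no structure shared by genes between libraries. Their SDs leave out that part of the spread, so they cannot say how unusual the difference is. With the 4 controls split 2 and 2, the 6 assignments gave correlations of 0.224 to 0.451, and covariances of 0.0273 to 0.0457. Genes called in both comparisons numbered 0 in edgeR, against 5.47e-05 for independent lists and 0 in the simulations. DESeq2 called 1, Siglec1, in both (2.47 and 2.55 on the log2 scale, DESeq2 adjusted p = 0.0145 and 0.00804). At an unadjusted p below 0.05, the comparisons had 1145 and 1039 genes.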

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

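No biological or technical explanation was tested for the values in this part, and the way of finding them was set before the data were examined. In each group of 4 libraries, the highest or lowest library was singled out where its gap to the nearest other library took up most of the range of the group (Dixon's ratio above its 95% critical value). Of 312 groups of values tested, over the library totals, 33 list scores and 70 named genes, 16 were singled out in this way. Chance flags about 1 in 20 groups, which is 15.6 of 312, so the number is close to that of chance.

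Control replicate 2 had 8.50 CPM of Ttr, where the other controls had 0.491 to 0.781. That library sets the mean of Ttr in the controls, and with it the sign of the knockdown value. Control replicate 3 had a total of 37166146 counts, against 22911948 to 24362582 in the other controls. The score of oligodendrocyte precursor genes was -0.252 in overexpression replicate 2, against 0.0321 to 0.0810 in the other overexpression libraries. The score of excitatory neuron genes was -0.308 in knockdown replicate 4, against 0.00551 to 0.0692 in the other knockdown libraries, and that library also had the highest interferon score (2.736) and the lowest myelin score (-0.902) of the 12.

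Among the controls, Cd8a had 0.0425 CPM in replicate 2 (others 0.0819 to 0.0868), which is below the 3-count floor of that library (0.125 CPM). Cd8a rested on 1 to 3 counts in every control library. Ctss had 69.7 CPM in control replicate 4 (others 77.9 to 79.6), Mrc1 had 1.87 CPM there (others 3.48 to 3.93), and Steap4 had 0.0868 CPM there (others 0.290 to 0.340), again below its floor of 0.131 CPM. In overexpression libraries, Col1a2 had 32.2 CPM in replicate 3 (others 21.8 to 23.2), P4ha1 had 41.7 CPM in replicate 1 (others 39.96 to 39.97), Per1 had 60.9 CPM in replicate 3 (others 70.2 to 71.6) and Vwf had 11.5 CPM in replicate 2 (others 17.9 to 18.4). In knockdown libraries, Ndnf had 14.9 CPM in replicate 1 (others 33.6 to 37.1) and Vim had 27.5 CPM in the same library (others 35.5 to 36.2). Slc16a12 had 2.60 CPM in knockdown replicate 3 (others 2.23 to 2.25), and Spry4 had 12.4 CPM in knockdown replicate 4 (others 15.8 to 16.5).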

How the results depend on the processing

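The covariate fits and the fits without 2 libraries at once were chosen after seeing the data, and all other alternatives before the data were examined. The 1 gene called in each comparison became 40, 42 and 4 genes in overexpression against control, knockdown against control and overexpression against knockdown with DESeq2, and 0, 1 and 0 with limma-voom. With no filter on low counts edgeR called 20, 22 and 1 genes of 34740. Fits of only the 2 groups compared called 0 genes in overexpression and 2 in knockdown, a fold threshold of 0.25 called 0 in knockdown, and robust dispersions called 0 in overexpression and 0 between overexpression and knockdown. On the deposited TPM with a pseudocount of 1 or of 0.1, 0 genes passed in knockdown and 2 between overexpression and knockdown, and with no filter 2 passed in overexpression and 3 between overexpression and knockdown. The cause of these differences between tools and filters was not tested. Ttr in overexpression kept its direction and lost its call with limma-voom (7.83), with only the 2 groups compared (7.01) and with robust dispersions (7.01). Against knockdown it lost its call with limma-voom (8.51) and robust dispersions (8.42).

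With the striatal score as covariate 4 genes passed in knockdown. With the mural and meningeal score as covariate 0 genes passed in overexpression (Ttr 8.19, with an SE of 1.31 in place of 0.81) and 0 in knockdown, and 10 and 8 lists passed in place of 19 and 16. Scores of overexpression libraries (0.303 to 1.015) lay above all those of controls (-0.967 to 0.138) and of knockdown libraries (-0.406 to 0.202). In both comparisons with overexpression these fits therefore cannot fully tell the score from the group. In overexpression against control that covariate turned Crabp2 to -0.61, Slc13a4 to -0.095, Kcnj13 to -0.65 and Cdh5 to -0.064. The calls on interferon-stimulated genes (0.0039), choroid plexus (0.081), reactive astrocyte (0.14), retinoid (0.15), activated microglia (0.19), homeostatic microglia (0.069), endothelial (0.049) and ependymal genes (0.61) ended there. It also turned the means of oxidative phosphorylation genes to 0.073, presynaptic genes to 0.0063, myelin genes to 0.038, ribosomal protein genes to 0.032 and excitatory neuron genes to 0.083. Of these, oxidative phosphorylation genes passed in the opposite direction (camera adjusted p = 0.000396) and the other 4 did not pass (0.215 to 0.968). In knockdown the calls on reactive astrocyte (0.16), presynaptic (-0.056), astrocyte identity (0.039), excitatory neuron (-0.078), mitochondrially encoded (0.0040), corticotropin-releasing hormone (0.15) and activated microglia genes (0.15) ended. Between overexpression and knockdown those on choroid plexus (0.010), antigen presentation (0.26), activated microglia (0.045) and ribosomal protein genes (-0.00019) and nuclear-retained RNAs (0.060) did, and the covariate turned reactive astrocyte genes to -0.015 and oxidative phosphorylation genes to 0.052, where the latter passed in the opposite direction (camera adjusted p = 0.00355). The cause was not tested. Without both knockdown libraries with high Xist counts, 0 genes passed in overexpression (Ttr 7.01), 0 in knockdown and 0 between overexpression and knockdown (Ttr 7.89), with fewer libraries in the fit. Without replicate 4 of overexpression and of knockdown, 17 genes passed in knockdown and 6 between overexpression and knockdown, and myelin genes turned to -0.092 between overexpression and knockdown.

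List counts were 0, 0 and 0 in camera with an estimated correlation, which asks the same question as with the preset one. The camera calls on lists thus rest on the preset correlation of 0.01. Counts were 0, 1 and 0 with fry for a single direction and 2, 1 and 0 with fry for either direction, tests that ask other questions than camera. The correlation of both sets of values against control (0.618) was 0.557 over genes of at least 10 CPM, 0.342 with the controls split, 0.557 without both knockdown libraries with high Xist counts and 0.443 without both replicates 4. Genes called in both comparisons numbered 0 in edgeR under each setting where the overlap was counted, and 1 in DESeq2 (Siglec1).

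Leaving out each library in turn gave 0 to 4, 0 to 10 and 0 to 2 genes in the 3 comparisons. Ttr ranged from 6.39 to 9.02 in overexpression, from -2.03 to 0.60 in knockdown and from 7.81 to 9.04 between overexpression and knockdown, and the sign turned in knockdown without control replicate 2 alone. The numbers of lists ranged from 16 to 21, 14 to 17 and 8 to 17, the correlation from 0.511 to 0.706, and the mean of myelin genes between overexpression and knockdown from -0.038, without knockdown replicate 4, to 0.32.

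The shared replicate numbers did not pair the libraries. Of the 12 same-numbered pairs 2 had a correlation of deviations above 0.1 (range -0.341 to 0.160), and 1 of 12 libraries correlated best with its own number. With the replicate number as a block 0 genes passed in knockdown and 2 between overexpression and knockdown. Named genes apart from Ttr, whose values are given above, mostly kept their direction and side of the threshold. They did so in 1100 of 1133 values in overexpression, 873 of 928 in knockdown and 705 of 711 between overexpression and knockdown. In these comparisons 29, 41 and 6 values passed that did not in the fit reported, and 0, 14 and 0 no longer passed. Among these genes only Nr4a1 in knockdown had a call to lose, so all 14 lost calls were its own. Lists that passed did so in 328 of 417, 267 of 351 and 201 of 285 values. Depth limits genes near the floor, since 3 counts amount to 0.0807 to 0.151 CPM, and Ttr had 3 to 47 counts in 7 of the 8 control and knockdown libraries.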

Other observations

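Of the tests in this part, those on single libraries (replicate 4 of knockdown, replicate 4 of overexpression) and on lymphocytes were chosen only after the result was seen, as were the genes named in the next paragraph. The tests with a striatal or a mural and meningeal score and that on clock genes were chosen after the patterns and the scores had been seen, though before their own results were. The splits were planned.

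Some genes not named in the comparisons stood apart by library or by group. Ighg2b, an antibody heavy chain, had 1925 counts in overexpression replicate 1 and 240 in overexpression replicate 4, against 0 to 52 in the other 10 libraries, and DESeq2 called it in overexpression against control (adjusted p = 0.0223). Rn7sk, a small nuclear RNA without a poly(A) tail, had 7, 8, 10 and 24 counts in knockdown replicates 1 to 4 and 8 in overexpression replicate 4, against 35 to 196 in the other 7 libraries. It was called in knockdown against control by DESeq2 (-3.20 on the log2 scale, adjusted p = 0.0401) and by edgeR with no filter on low counts (-3.27, adjusted p = 0.0474). Xist, the RNA that silences an X chromosome in female cells, had 322 and 547 counts in knockdown replicates 1 and 3, against 11 to 65 in the other 10. The Y-linked genes Ddx3y (1283 to 2760 counts) and Uty (303 to 630 counts) were counted in all 12 libraries, which the labels give as male. Striatal scores spread from -1.281 to 1.482 and differed mostly within groups, with Drd2 at 43 counts in control replicate 1 and 781 in control replicate 4.

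Immediate early genes were higher in knockdown than in control by a mean of 0.63. A different share of striatum in the tissue was argued against by the striatal scores, whose means differed little beside their spread. They were -0.155 ± 1.06 in controls and -0.00704 ± 1.08 in knockdown (SD, n = 4). With that score as covariate 0.976 of the mean was left (0.885 to 1.07 with each library left out). The covariate had little difference between the groups to remove, so that share adds little. Another time of day at collection was argued against as far as 8 clock genes of one phase and 4 of the opposite phase differed by -0.0200 on the log2 scale (-0.0848 to 0.0461 with each library left out). That value is a difference of means over genes that went both ways. Per2 of the first set (0.34 with an SE of 0.13) and Cry1 of the second (0.19 with an SE of 0.08) were both higher, as was Per1, which was in neither set, so a shift in time is not ruled out in full. An effect of the hairpin against Ttr may lie behind the pattern, as a hypothesis, since handling of the mice, the source of the vector and an off-target effect of the hairpin go with the groups or were not recorded and stay open. Ttr itself was not measurably lower in these libraries.

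Interferon-stimulated genes were higher in knockdown than in control by a mean of 1.90. The pattern was not in knockdown replicate 4 alone, since 0.689 of the mean was left without it, and the lowest score of the other knockdown libraries (-0.0920) lay above the highest control (-0.567). Lymphocytes in the tissue were argued against as its whole source, since between overexpression and knockdown their genes were higher by 0.884 (0.503 to 1.21 with each library left out) where interferon-stimulated genes were lower (-1.34 to -0.398). That comparison does not measure what lymphocytes add in knockdown against control. There the mean lymphocyte score was -0.166 ± 0.361 in knockdown and -0.552 ± 0.0982 in controls (SD, n = 4), so a partial contribution stays open. A response to the vector or the hairpin, both of which differ between the groups, may explain the interferon pattern, and the design cannot separate these from an effect of Ttr.

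Antigen presentation genes were higher in overexpression than in control by a mean of 1.45. With the mural and meningeal score as covariate 0.608 of that mean was left, but the share ran from 0.346 to 0.839 with each library left out, so more meninges and vessel wall in the tissue stays open as a partial source. Without overexpression replicate 4 0.608 of the mean was left, but overexpression replicate 2 (-0.614) lay below the highest control (-0.424), so an origin in a few libraries and an effect of the group cannot be told apart with 4 libraries. Lymphocyte and antibody genes were highest in overexpression replicates 1 and 4, and an immune response to the vector or its protein in those mice may contribute.

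Each comparison was set against the 35 splits of its 8 libraries into 4 and 4. In each of the 3 comparisons 1 split, the real one, gave as many changed genes in edgeR (1 gene, and 0 in the highest other split). In both comparisons with overexpression that gene was Ttr, which the virus carries, so the design fixed the outcome and the count says nothing on chance in any response. In knockdown against control the gene was Nr4a1. To rank first of 35 is the most that these splits can show, and it rests on 1 gene against 0, so chance is not excluded. The count in knockdown was also 0 with the replicate number as a block, with a fold threshold and with the mural and meningeal score as covariate. It was 0 on the deposited TPM with a pseudocount of 1 or of 0.1, and without both knockdown libraries with high Xist counts. On TPM with no filter the 1 gene called was not Nr4a1. With a library left out the count fell to 0 in 4, 7 and 3 of 12 fits in overexpression against control, knockdown against control and overexpression against knockdown. At an unadjusted p below 0.05, 11, 7 and 20 of 35 splits gave as many genes as the real one. Chance cannot be excluded for the numbers of lists either. As many lists as the real 19 passed in 4 of 35 splits in overexpression against control (highest other 22). In knockdown against control 8 of 35 splits gave as many as the real 16 (highest other 19), and between overexpression and knockdown 16 of 35 gave as many as the real 13 (highest other 20). By unadjusted p the highest other splits gave 2780, 2367 and 1973 genes, against 1145, 1039 and 932 in the real ones. The split with 2780 genes, in overexpression against control, followed the striatal scores, which was seen only after the counts. Control replicates 1 and 3 and overexpression replicates 2 and 3 (-1.281 to -0.214) stood against the other libraries (0.187 to 1.482). The splits with 2367 and 1973 genes followed that score only in part. The samples of overexpression against control thus hold a structure that the groups do not follow, and no further test of it was run.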
